A study of Homo sapiens with 6 samples.

How the data were processed

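RNA of Ishikawa cells was harvested after treatment with DMSO or 5 µM penfluridol, and messenger RNA libraries were made from total RNA with a SMARTer kit, per the labels' protocols. The 6 samples were put into 2 groups of 3 by the treatment named in their labels, and the replicate numbers are those of the sample titles. One deposited table held all 6 libraries, and each column was matched to its sample by its name. The table had 0 columns of other samples, and 1 of its lines had been emptied before it was used here.

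The deposited values are TPM, transcript abundances that the authors had scaled to a fixed total within each library and rounded to 2 decimals. The unit follows from the values, since all columns summed to nearly the same total, from 994165 to 997207, and the file header names none. The submitters' processing notes name fastp, RSEM and the genome build GRCh38.p13. Their versions, the aligner and the annotation are not given in the sources used here. TPM divides by transcript length and by the library's total, so a value is relative to all other transcripts of that library, and a rise of abundant transcripts lowers the others. It keeps no read counts. The depth per library is therefore unknown, and the precision of a value was taken from the spread between the 3 libraries of a group.

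The table paired gene identifiers with symbols for 60670 genes. Of these, 58452 identifiers matched GENCODE release 29 (GRCh38), from which gene positions, gene types, transcript GC content and transcript length were taken, the last 2 as the median over a gene's transcripts. Among the 12201 genes tested 12112 (99.3%) had GC content and length, and 10628 were protein-coding. Positions are 1-based.

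The test planned before the data were examined was a count test with a set of count alternatives. Since the table holds TPM, the test fixed for that case was used in its place. It was a linear model with an intercept and treatment, on log2(TPM + 1), in genes with a mean of at least 1 TPM, fitted with limma 3.58.1 in R 4.3.3 with moderated variances that follow a trend with mean expression. P-values are two-sided and were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 made a call. Errors of fold changes are the moderated standard errors (SE), with a median over all genes of 0.238. Gene lists, 28 in all, were fixed before the data were examined, and the 26 lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. No list passed with an estimated correlation, where the smallest adjusted p was 0.157, while 11 passed with the preset one, 6 higher and 5 lower. The size of the correlation alone does not account for every lost call. The interferon list had an estimate of -0.0114, below the preset one, and its camera adjusted p still moved from 0.00113 to 0.165. Among the lists that passed, the estimate reached 0.513, for heat shock. A list's count adjusted over the list alone used the same p-values, adjusted over its measured members.

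Genes were named by a rule fixed before the data were examined. It took, among called genes with a symbol, a mean of at least 5 TPM and no overlap between the groups, the 4 with the largest increase and the 4 with the largest decrease. It also took from each main list the member with the smallest p, or the 2 with the smallest where the list passed, and from each control list the member with the highest mean TPM. A symbol counted as such where the table's gene description credits the human gene nomenclature. Other genes were named after their values were seen, and 1 gene that the rule took is not reported here.

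The model was tested on simulated data with the means and spreads of the 12201 real genes, independent noise and 200 changed genes. Of 100 planted log2 changes of 1, 57% were called, and of 100 planted changes of 2, 84%. There were 4 false calls, and 0 calls where nothing was planted. The recovery rates hold for the planted genes under independent noise alone. Genes of the real libraries shifted together along transcript GC content, which independent noise leaves out. Neither the recovery rates nor the numbers of false calls can therefore be carried over to the real data.

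Libraries were compared before averaging. Pearson's correlation of log2(TPM + 1) was 0.930 to 0.960 between DMSO libraries and 0.970 to 0.982 between penfluridol libraries. Between the groups it was 0.895 to 0.955. DMSO 3 correlated at 0.955, 0.955 and 0.945 with penfluridol 1, 2 and 3, against 0.956 with DMSO 1 and 0.930 with DMSO 2. A pair of libraries had 71 to 143 identical values among the genes tested, so each library was kept as its own replicate.

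Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low TPM, a filter of at least 5 TPM in at least 3 libraries, the replicate number as a block, an estimated correlation in the set test, and leaving out each library in turn. Alternatives added after seeing the data were median-of-ratios scaling of the TPM values, a GC and length correction alone and without DMSO 3, and a fit of protein-coding genes alone with TPM rescaled to them. The GC and length correction subtracted from each library a local regression (loess, span 0.5, degree 1) of a gene's deviation from its mean on transcript GC content and log2 length. Pathways named in the deposited table with at least 10 tested genes were also tested, after seeing the data. Tables and figures were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.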

Results

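Ishikawa cells, a line derived from a human endometrial adenocarcinoma, were treated with 5 µM penfluridol or with its solvent DMSO, and messenger RNA was sequenced from 3 libraries per group. Penfluridol is a long-acting antipsychotic of the diphenylbutylpiperidine class that blocks dopamine receptors and T-type calcium channels, and it is a cationic amphiphilic compound. The length of the treatment is not given in the sources used here. Expression was given per gene as TPM, transcript abundance scaled to a fixed total per library, for 60670 genes, of which 26597 were above 0 in at least 1 library and 12201 had a mean of at least 1 TPM and were tested. TPM values keep no record of how many reads lay behind them, so the sequencing depth is unknown and no counting interval can be given. Each library summed to between 994165 and 997207 TPM. The labels number the libraries 1 to 3 within each group and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

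The comparison of penfluridol with DMSO asks which transcripts differ in abundance after exposure to the drug. Transcripts of the stress-induced genes NUPR1, INHBE, TRIB3 and GDF15 had the 4 largest increases among genes that met the rule for naming. GDF15, a secreted stress cytokine, rose from 66.8 ± 7.03 to 922 ± 16.7 TPM (SD, n = 3 per group), a log2 fold change of 3.77 (SE 0.11, adjusted p = 4.54e-05, limma). TRIB3, a pseudokinase that acts in feedback on ATF4 and CHOP, rose from 19.2 ± 3.40 to 275 ± 16.4 TPM, a log2 fold change of 3.78 (SE 0.15, adjusted p = 8.41e-05). NUPR1, a small chromatin-associated stress protein, rose from 4.62 ± 1.46 to 93.8 ± 10.9 TPM (log2 fold change 4.10, SE 0.21, adjusted p = 0.000249), and INHBE, which encodes an activin subunit, from 2.21 ± 0.254 to 46.7 ± 2.09 TPM (log2 fold change 3.90, SE 0.15, adjusted p = 8.41e-05). In the GRCh38 assembly GDF15 (ENSG00000130513) lies on chromosome 19 from 18374731 to 18389176, TRIB3 (ENSG00000101255) on chromosome 20 from 362835 to 397559, NUPR1 (ENSG00000176046) on chromosome 16 from 28532708 to 28539174 and INHBE (ENSG00000139269) on chromosome 12 from 57452323 to 57459280. All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

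Among the protein-coding genes that fell, 4 were chosen after their values were seen, since the rule for naming took small non-coding RNAs alone. DHRS2, a short-chain dehydrogenase/reductase, fell from 55.1 ± 4.02 to 6.36 ± 0.846 TPM (log2 fold change -2.94, SE 0.15, adjusted p = 0.000238). HSP90AA1, the inducible cytosolic HSP90 chaperone, fell from 52.0 ± 39.9 to 7.14 ± 2.42 TPM, a log2 fold change of -2.45 (SE 0.56, adjusted p = 0.0327). TMSB15A, an actin-binding thymosin with near-identical paralogs that can share its reads, fell by 2.35 on the log2 scale (SE 0.26, adjusted p = 0.00345), and VSNL1, a neuronal calcium sensor, fell by 2.15 (SE 0.36, adjusted p = 0.0120). With 1 library left out, the call of HSP90AA1 held only without DMSO 3, with adjusted p-values of 0.0552 to 0.113 otherwise, and that of VSNL1 was lost without DMSO 1 (0.0623), penfluridol 1 (0.0549) or penfluridol 2 (0.0538). The 4 transcripts taken by the rule were the U2 spliceosomal RNA gene RNU2-1 and the 5S ribosomal RNA genes RNA5S8, RNA5S9 and RNA5S2. RNU2-1 was listed at 70.0, 33.1 and 39.6 TPM in the DMSO libraries and at 0, 0 and 1.89 TPM in the penfluridol libraries (adjusted p = 0.00207). RNA5S8 was listed at 2277, 383 and 168 TPM in DMSO and at 0 in all 3 penfluridol libraries (adjusted p = 0.00192), and RNA5S9 at 221, 39.4 and 39.9 TPM in DMSO and likewise at 0 with penfluridol (adjusted p = 0.00263). RNA5S2 was listed at 1850, 215 and 605 TPM in DMSO and at 0, 22.4 and 0 TPM with penfluridol (adjusted p = 0.0133, or 0.0561 without DMSO 1 and 0.0567 without penfluridol 1). These 4 genes belong to families of near-identical copies whose reads cannot be assigned with certainty, so their values are uncertain. The share of small non-coding RNA in all TPM was 3.97%, 0.686% and 1.64% in the DMSO libraries and 0.470%, 0.248% and 0.259% in the penfluridol libraries.

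**Figure D1:**
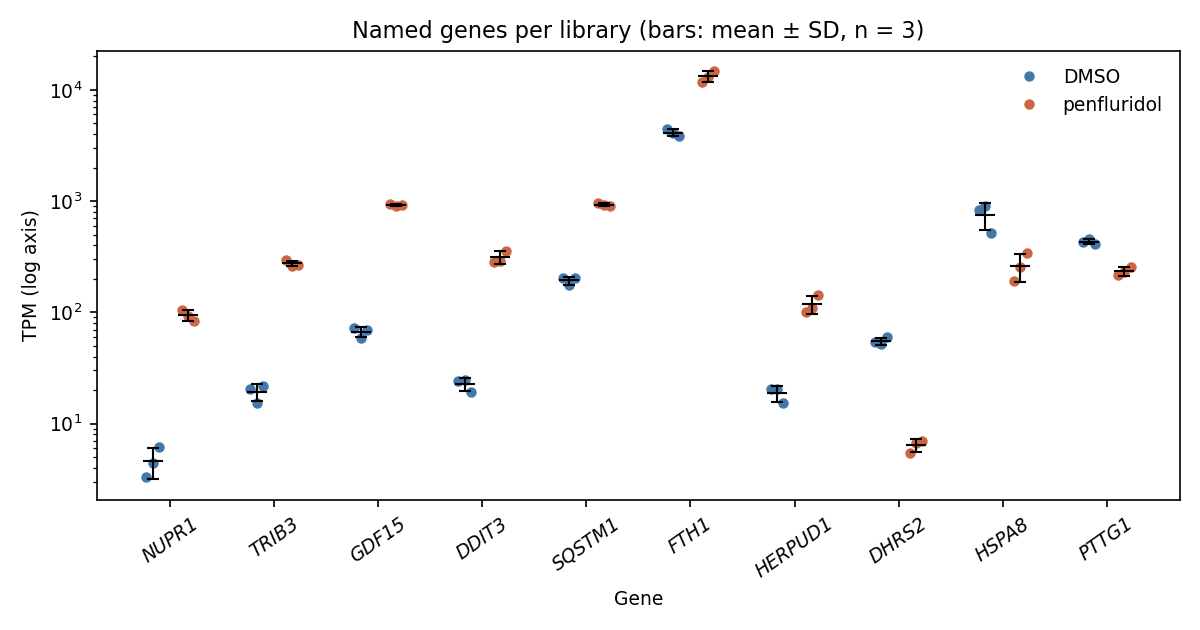
TPM on a log axis for 10 genes (x axis) in each of the 6 libraries, DMSO in blue and penfluridol in red, with the mean and SD of the 3 libraries as black bars. NUPR1, TRIB3, GDF15, DDIT3, SQSTM1, FTH1 and HERPUD1 were higher in each penfluridol library than in each DMSO library, and DHRS2, HSPA8 and PTTG1 were lower.

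Across all 12201 genes tested, 1190 were higher and 425 lower with penfluridol at an adjusted p under 0.05, so that 73.7% of the calls were increases. Of these, 423 were at least 2-fold higher and 224 at least 2-fold lower. In each called gene the 3 penfluridol values lay all above or all below the 3 DMSO values. Such separation occurred in 4513 of the tested genes (37.0%), where chance gives 10% for a gene taken alone. Genes of a library shift together, so the excess is not a count of genes that the drug changed. The numbers of calls depended on the libraries: with 1 library left out, 333 genes were higher and 60 lower without DMSO 1, 648 and 187 without DMSO 2, 1732 and 2380 without DMSO 3, 452 and 81 without penfluridol 1, 214 and 42 without penfluridol 2, and 640 and 212 without penfluridol 3. The split of calls also moved with scaling, to 997 higher and 719 lower (58.1% higher) with median-of-ratios scaling and to 1268 higher and 1014 lower (55.6% higher) after removal of each library's trend with transcript GC content and length.

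Genes of the amino acid response, the targets of the transcription factor ATF4, rose together. Of 31 measured members 23 rose, none fell and 8 did not pass, and adjusted over the list alone 24 rose and 1 fell. The median log2 fold change of the list was 1.28 (camera adjusted p = 1.87e-16, and adjusted p = 0.157 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, rose from 22.6 ± 2.99 to 312 ± 41.1 TPM (log2 fold change 3.73, SE 0.15, adjusted p = 8.41e-05). ATF4 itself rose from 443 ± 24.5 to 801 ± 98.0 TPM (log2 fold change 0.85, SE 0.12, adjusted p = 0.00728). FGF21, a secreted metabolic hormone, went from 0.0800 ± 0.0346 to 9.15 ± 1.29 TPM (adjusted p = 0.000669), and ASNS, asparagine synthetase, from 30.5 ± 6.75 to 84.1 ± 18.1 TPM (adjusted p = 0.00963). The subunits of the heterodimeric amino acid transporter, SLC7A5 and SLC3A2, rose by log2 fold changes of 1.40 and 1.38. The 8 members that did not pass included SLC7A11, at 1.98 ± 1.17 TPM in DMSO and 1.54 ± 0.292 TPM with penfluridol, and SLC38A2, at 14.7 ± 12.02 and 4.16 ± 1.57 TPM. After the GC and length correction the list kept a median log2 fold change of 1.03 (adjusted p = 0.0169 with an estimated correlation). ATF4, FGF21, ASNS, SLC7A5, SLC3A2 and the other list members named beyond the rule were chosen after their values were seen.

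The unfolded protein response list, which holds chaperones and degradation factors of the endoplasmic reticulum, did not pass as a group. Of 21 measured members 3 rose and none fell, and adjusted over the list alone 4 rose and 2 fell. The median log2 fold change was -0.07 while the set test pointed upward (camera adjusted p = 0.594), and after the GC and length correction it passed (adjusted p = 0.0442, and adjusted p = 0.2997 with an estimated correlation). The 3 that rose were HERPUD1, a component of endoplasmic-reticulum-associated degradation, from 18.7 ± 2.96 to 119 ± 22.6 TPM (log2 fold change 2.59, SE 0.18, adjusted p = 0.000826), the chaperone HYOU1 (log2 fold change 1.45, adjusted p = 0.00142) and the ubiquitin ligase SYVN1 (log2 fold change 0.82, adjusted p = 0.0210). HSPA5, which encodes the chaperone BiP, did not pass, at 77.5 ± 28.6 TPM in DMSO and 154 ± 34.6 TPM with penfluridol (adjusted p = 0.0640, or 0.000706 after the GC and length correction). With that correction 5 members were called higher and 2 lower. The 2 lower ones, which also fell when adjusted over the list alone, were HSP90B1 and CRELD2. HSP90B1 was at 172 ± 110 TPM in DMSO and 46.7 ± 9.82 TPM with penfluridol (limma adjusted p = 0.0573, or 0.0217 after the correction). CRELD2 was at 126 ± 16.3 and 93.2 ± 2.64 TPM (0.0658, or 0.00375 after the correction).

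Lysosome and autophagy genes of the CLEAR network, the targets of TFEB, were higher as a group. Of 33 measured members 10 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell. The median log2 fold change was 0.39 (camera adjusted p = 0.00113, and adjusted p = 0.579 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose from 193 ± 16.3 to 925 ± 29.3 TPM (log2 fold change 2.26, SE 0.10, adjusted p = 0.000186). PSAP, the precursor of the saposins that aid lysosomal sphingolipid breakdown, rose from 303 ± 24.6 to 568 ± 24.6 TPM (log2 fold change 0.91, SE 0.10, adjusted p = 0.00395). The single member that fell was the protease gene CTSB, from 548 ± 41.7 to 369 ± 36.6 TPM (log2 fold change -0.57, adjusted p = 0.0240). Of 17 measured NRF2 and oxidative stress genes 6 rose and none fell, and adjusted over the list alone 7 rose and 1 fell. Their median log2 fold change was 0.41 (camera adjusted p = 0.0200, and adjusted p = 0.375 with an estimated correlation). FTH1, the ferritin heavy chain, rose from 4123 ± 294 to 13217 ± 1467 TPM (log2 fold change 1.68, SE 0.13, adjusted p = 0.00122), although its processed pseudogenes can share reads with it. OSGIN1, an oxidative stress response gene, rose from 4.39 ± 0.850 to 23.3 ± 1.57 TPM (log2 fold change 2.18, SE 0.18, adjusted p = 0.00131). The other 4 that rose were HMOX1, NQO1, SRXN1 and FTL. The NRF2 list lost its call without DMSO 3 (adjusted p = 0.0902), and its median moved to 0.89 after the GC and length correction.

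Inflammatory, interferon-stimulated and immediate early genes were higher with penfluridol. Of 12 measured NF-kB targets 9 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 1.12 (camera adjusted p = 6.09e-06, and adjusted p = 0.157 with an estimated correlation). IL32, a pro-inflammatory cytokine, rose from 1.06 ± 0.390 to 18.6 ± 1.87 TPM (log2 fold change 3.26, SE 0.21, adjusted p = 0.000669), and NFKB2, the p100 precursor of a NF-kB subunit, from 19.4 ± 1.26 to 62.3 ± 4.18 TPM (log2 fold change 1.63, SE 0.12, adjusted p = 0.00114). Of 24 measured immediate early genes 13 rose and none fell, and adjusted over the list alone 18 rose. Their median log2 fold change was 1.20 (camera adjusted p = 1.54e-08, and adjusted p = 0.388 with an estimated correlation). JUNB, a subunit of the transcription factor AP-1, rose from 27.1 ± 2.97 to 78.3 ± 4.70 TPM (log2 fold change 1.50, SE 0.13, adjusted p = 0.00151), and IER3 from 8.61 ± 0.730 to 26.8 ± 2.08 TPM (log2 fold change 1.53, SE 0.14, adjusted p = 0.00205). Of 13 measured interferon response genes 6 rose and none fell, and adjusted over the list alone 10 rose. Their median log2 fold change was 0.70 (camera adjusted p = 0.00113, and adjusted p = 0.165 with an estimated correlation). IRF7, a transcription factor of interferon genes, rose from 4.71 ± 0.289 to 17.0 ± 1.41 TPM (log2 fold change 1.65, SE 0.16, adjusted p = 0.00207). IFI27 rose from 8.78 ± 1.65 to 18.7 ± 2.38 TPM (log2 fold change 1.02, SE 0.18, adjusted p = 0.0161), a call that was lost without DMSO 1 (0.0817), penfluridol 1 (0.0681) or penfluridol 2 (0.0735). The NF-kB, interferon and immediate early lists had median GC contents of 56.4%, 56.4% and 57.8%, against 51.8% for all genes tested. After the GC and length correction their medians were 1.09, 0.66 and 0.88. Each still passed with camera's preset correlation, but none with an estimated one (adjusted p = 0.0521, 0.134 and 0.241). The correction left 1 NF-kB target called lower.

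Cell cycle genes were lower as groups. Of 30 measured genes of mitosis and G2/M phase 5 fell and none rose, and adjusted over the list alone 18 fell. Their median log2 fold change was -1.04 (camera adjusted p = 2.07e-08, and adjusted p = 0.388 with an estimated correlation). PTTG1, the separase inhibitor securin, fell from 433 ± 21.8 to 234 ± 21.03 TPM (log2 fold change -0.89, SE 0.11, adjusted p = 0.00469), and CCNB1, cyclin B1, from 120 ± 21.2 to 62.7 ± 15.96 TPM (log2 fold change -0.94, SE 0.21, adjusted p = 0.0312). The other 3 were CCNB2, DLGAP5 and ECT2. The transcripts of this list had a median GC content of 45.2%, against 51.8% for all genes tested, and the GC and length correction moved its median to -0.59 (camera adjusted p = 1.53e-08, and adjusted p = 0.0299 with an estimated correlation), while the number of members called lower went from 5 to 13. It ended the calls of PTTG1 (log2 fold change -0.49, adjusted p = 0.0859) and ECT2 (0.0507). CCNB1 had a log2 fold change of -0.50 after the correction (adjusted p = 0.0317, or 0.0521 when DMSO 3 was also left out), and its call before the correction was lost without DMSO 1 (0.120), DMSO 2 (0.0890), penfluridol 1 (0.105) or penfluridol 2 (0.138). Of 34 measured genes of DNA replication and S phase 1 rose and 2 fell, with none adjusted over the list alone, and the median log2 fold change was -0.43 (camera adjusted p = 0.000805, and adjusted p = 0.625 with an estimated correlation). After the GC and length correction 13 members of this list were called lower and none higher. CDT1, a replication licensing factor, was the member that rose, from 56.9 ± 9.20 to 87.7 ± 7.57 TPM (log2 fold change 0.62, SE 0.15, adjusted p = 0.0353). GINS2, a subunit of the replicative helicase, fell from 16.4 ± 1.57 to 9.30 ± 1.79 TPM (log2 fold change -0.77, SE 0.18, adjusted p = 0.0356), and RRM1, the large subunit of ribonucleotide reductase, from 22.5 ± 9.80 to 7.11 ± 2.12 TPM (adjusted p = 0.0418). The call of CDT1 was lost after the GC and length correction (log2 fold change 0.25, adjusted p = 0.102) and with any library but DMSO 3 left out (adjusted p = 0.0637 to 0.146), and that of GINS2 without DMSO 1 (0.121), DMSO 2 (0.0767), penfluridol 1 (0.112) or penfluridol 2 (0.145). Of 12 measured replication-dependent histone genes, kept as a control list since most of their transcripts lack a poly(A) tail, 6 fell and none rose, and adjusted over the list alone 10 fell. Their median log2 fold change was -0.86 (camera adjusted p = 6.09e-06, and adjusted p = 0.169 with an estimated correlation). H2BC12 had the highest mean TPM among them and fell from 66.4 ± 2.72 to 26.9 ± 4.36 TPM (log2 fold change -1.29, SE 0.14, adjusted p = 0.00348), and like other histone genes it has close paralogs that can share its reads.

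Heat shock and respiratory chain genes were also lower as groups. Of 15 measured heat shock genes 3 fell and none rose, and adjusted over the list alone 8 fell and 2 rose. Their median log2 fold change was -0.72 (camera adjusted p = 0.00656, and adjusted p = 0.698 with an estimated correlation), and 8 were called lower after the GC and length correction. The 3 that fell were HSP90AA1, HSPA8 and HSPE1. HSPA8, the constitutive HSP70 chaperone, fell from 752 ± 204 to 262 ± 74.2 TPM (log2 fold change -1.52, SE 0.27, adjusted p = 0.0159), and HSPE1, a mitochondrial co-chaperonin, from 664 ± 239 to 241 ± 33.1 TPM (log2 fold change -1.40, SE 0.27, adjusted p = 0.0202). All 3 genes have processed pseudogenes that can share reads with them. Without DMSO 1, penfluridol 1 or penfluridol 2 the adjusted p of HSPA8 was 0.0708, 0.0567 and 0.0778, and that of HSPE1 was 0.0838, 0.0787 and 0.0986. Of 43 measured genes of oxidative phosphorylation 4 fell and none rose, with none adjusted over the list alone, and the median log2 fold change was -0.23 (camera adjusted p = 0.00176, and adjusted p = 0.169 with an estimated correlation). ATP5MC3, a subunit of the ATP synthase ring, fell from 306 ± 35.3 to 207 ± 6.95 TPM (log2 fold change -0.56, SE 0.11, adjusted p = 0.0231), and NDUFC1, a subunit of complex I, from 265 ± 17.3 to 172 ± 27.5 TPM (log2 fold change -0.63, SE 0.14, adjusted p = 0.0278). The other members that fell were COX7B, whose call was lost with the GC and length correction (0.149), and ATP5F1C. After the GC and length correction the list no longer passed (adjusted p = 0.0691), nor did ATP5MC3 (log2 fold change -0.17, adjusted p = 0.707), whose call was also lost without DMSO 1 (0.0729), penfluridol 1 (0.0810), penfluridol 2 (0.111) or penfluridol 3 (0.0680). NDUFC1 was lost without DMSO 1 (0.115), DMSO 2 (0.0753), penfluridol 1 (0.0981) or penfluridol 2 (0.140).

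**Figure D2:**
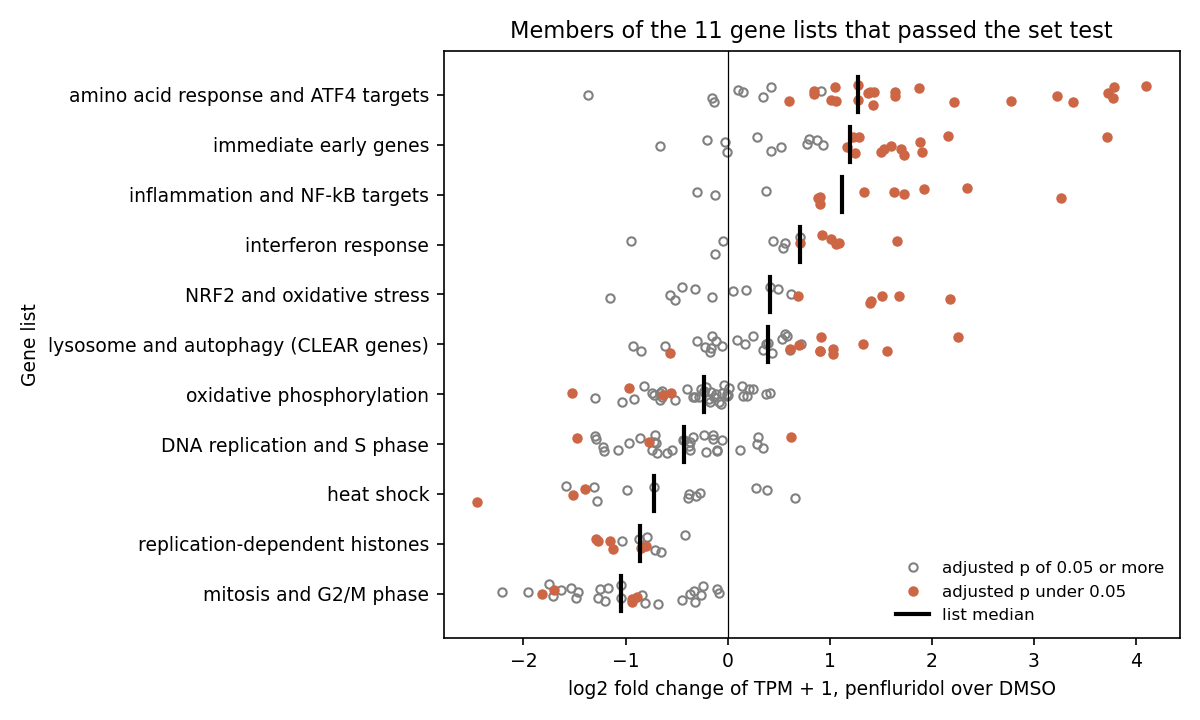
Log2 fold change of TPM + 1 between penfluridol and DMSO (x axis) for each measured member of the 11 gene lists that passed the set test with the preset correlation (y axis), filled where the adjusted p was under 0.05, with a black line at the list's median. The ATF4 list has a median of 1.28 and the mitosis list one of -1.04.

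Lipid gene lists did not pass the set test. Of 25 measured cholesterol synthesis genes 4 rose and 2 fell, also when adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 0.379). Among those that rose were SREBF2, a transcription factor of sterol synthesis, from 40.3 ± 2.49 to 65.3 ± 14.2 TPM (log2 fold change 0.66, SE 0.17, adjusted p = 0.0470), and MVD, an enzyme of the mevalonate pathway (log2 fold change 0.45, adjusted p = 0.0402). After the GC and length correction neither was called (adjusted p = 0.0587 and 0.562). TM7SF2 and ACAT2 fell. With the correction 2 members were called higher and 3 lower, and the median was -0.06. Of 15 fatty acid and lipid synthesis genes 1 fell, with none adjusted over the list alone (median -0.31, camera adjusted p = 0.238). That member was SREBF1, a transcription factor of lipid synthesis, at 57.3 ± 6.96 TPM in DMSO and 35.3 ± 6.24 TPM with penfluridol (log2 fold change -0.69, SE 0.17, adjusted p = 0.0377), and its call was lost without DMSO 1 (0.0833), DMSO 2 (0.0969), penfluridol 1 (0.122) or penfluridol 2 (0.157). Of 25 sphingolipid and phospholipid genes 4 rose and 1 fell, also adjusted over the list alone (median -0.09 with a set test that pointed upward, camera adjusted p = 0.928). SPHK1, sphingosine kinase, rose from 6.08 ± 0.520 to 20.03 ± 2.49 TPM (log2 fold change 1.57, SE 0.16, adjusted p = 0.00289). Of 8 LXR targets of sterol efflux 2 rose and 2 fell, also adjusted over the list alone (median -0.10 with a set test that pointed upward, camera adjusted p = 0.965). APOE, apolipoprotein E, rose from 48.1 ± 8.10 to 123 ± 8.65 TPM (log2 fold change 1.35, SE 0.15, adjusted p = 0.00344). Of 21 genes listed as reported penfluridol targets, 3 reached 1 TPM, of which 1 rose, also adjusted over the list alone (median -0.13 with a set test that pointed upward, camera adjusted p = 0.965). SMPD1, acid sphingomyelinase, was at 25.2 ± 3.58 TPM in DMSO and 42.0 ± 7.29 TPM with penfluridol (log2 fold change 0.71, SE 0.17, adjusted p = 0.0384), and its call was lost after the GC and length correction (0.0701) and with any library but DMSO 3 left out (0.0879 to 0.131). With the correction 3 fatty acid and lipid synthesis genes were called lower and 2 sphingolipid and phospholipid genes higher.

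The p53 target list did not pass (camera adjusted p = 0.113), although 7 of its 22 measured members rose and none fell, with 7 higher and 1 lower adjusted over the list alone. They were GDF15, SESN2, CDKN1A, PLK3, BBC3, TNFRSF10B and AEN, of which GDF15 and SESN2 are also in the ATF4 list and AEN was not called after the GC and length correction (0.0572). Of 23 apoptosis regulators 4 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (median log2 fold change 0.13, mean -0.0019, camera adjusted p = 0.528). BBC3, the BH3-only protein PUMA, rose from 6.88 ± 0.816 to 15.6 ± 1.49 TPM (log2 fold change 1.08, SE 0.17, adjusted p = 0.00953), with a log2 fold change of 0.67 after the GC and length correction and a call lost without DMSO 1 (0.0561) or penfluridol 2 (0.0782). Of 32 glycolysis and hypoxia genes 4 rose and 2 fell, and 7 and 4 adjusted over the list alone (median -0.15, mean 0.0073, camera adjusted p = 0.895). ENO2, a glycolytic enolase, rose from 24.99 ± 3.69 to 60.9 ± 2.45 TPM (log2 fold change 1.26, SE 0.14, adjusted p = 0.00334). Of 28 MYC targets and ribosome biogenesis genes 3 rose and 3 fell, and 4 and 4 adjusted over the list alone (median -0.25, camera adjusted p = 0.451). That list passed as lower after the GC and length correction (adjusted p = 0.0470, and adjusted p = 0.232 with an estimated correlation). PES1, a ribosome assembly factor, rose from 90.3 ± 12.3 to 160 ± 2.52 TPM (log2 fold change 0.83, SE 0.13, adjusted p = 0.00926), a call lost without DMSO 1 (0.0503) or penfluridol 2 (0.0678). Of 13 oestrogen and progesterone receptor signalling genes 2 rose and 2 fell, and 2 and 4 adjusted over the list alone (median -0.42, camera adjusted p = 0.524). CTSD, the lysosomal protease cathepsin D, rose from 202 ± 35.2 to 376 ± 12.5 TPM (log2 fold change 0.91, SE 0.14, adjusted p = 0.00980), with 0.53 after the GC and length correction and a call lost without DMSO 1 (0.0531) or penfluridol 2 (0.0687). Of 22 epithelial and mesenchymal genes 4 rose and 2 fell, and 5 and 5 adjusted over the list alone (median -0.21, camera adjusted p = 0.928). The tight junction gene CLDN7 rose from 209 ± 26.4 to 409 ± 12.2 TPM (log2 fold change 0.97, SE 0.12, adjusted p = 0.00488), and the keratin gene KRT8 fell from 1988 ± 231 to 1109 ± 86.1 TPM (log2 fold change -0.84, adjusted p = 0.00903). With the GC and length correction 7 members of the glycolysis list, 6 of the MYC list and 6 of the epithelial and mesenchymal list were called lower, against 2, 3 and 2 without it.

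Markers of other cell types were scarce. Of 10 fibroblast and stromal markers only COL1A1 reached a mean of 1 TPM, at 2.27 ± 0.365 TPM in DMSO and 2.70 ± 1.51 TPM with penfluridol (adjusted p = 0.824). Of 12 leukocyte markers 3 did, with 1 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.928). CD52, the one with the highest mean, fell from 7.15 ± 0.685 to 3.19 ± 0.0173 TPM (adjusted p = 0.0174), a call lost without DMSO 1 (0.0982), penfluridol 1 (0.0670) or penfluridol 2 (0.103). CD68, a lysosomal protein of macrophages, rose from 0.723 ± 0.332 to 4.62 ± 0.210 TPM (log2 fold change 1.72, SE 0.23, adjusted p = 0.00653). None of the 8 endothelial markers reached 1 TPM. Of 13 mitochondrially encoded messenger RNAs 1 fell and none rose, also adjusted over the list alone (median log2 fold change -0.08, or 0.42 after the GC and length correction, camera adjusted p = 0.666). It was MT-ND3, at 4115 ± 241 TPM in DMSO and 2603 ± 445 TPM with penfluridol (log2 fold change -0.67, adjusted p = 0.0269). After the GC and length correction its log2 fold change was 0.05, and its call was lost without DMSO 1 (0.110), DMSO 2 (0.0752), penfluridol 1 (0.102) or penfluridol 2 (0.140). Of 48 cytosolic ribosomal protein genes none was called in the limma test, in which 4029 of all genes had an unadjusted p under 0.05, and none was called adjusted over the list alone (median 0.07, camera adjusted p = 0.545). RPS2 stood at 14865 ± 1603 TPM in DMSO and 18931 ± 2978 TPM with penfluridol (adjusted p = 0.187).

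Libraries of 1 group differed along transcript GC content, and DMSO 3 lay nearer to the penfluridol libraries than the other DMSO libraries did. On the first principal component of the tested genes, which held 54.5% of the variance, DMSO 1, 2 and 3 stood at -45.1, -66.3 and 3.96 and penfluridol 1, 2 and 3 at 49.6, 37.2 and 20.7. Spearman's correlation between expression and transcript GC content, taken across genes within a library, was 0.197, 0.0818 and 0.333 in the DMSO libraries and 0.412, 0.385 and 0.344 in the penfluridol libraries. Genes are not independent replicates in such a correlation, and an exact permutation test of the 3 values against 3 cannot give a two-sided p below 0.1, which was its value here. Over genes, the log2 fold change followed GC content with a Spearman's rho of 0.602 and transcript length with one of 0.0558. Among the 2424 genes of lowest GC content, 28.7% to 43.9%, the median log2 fold change was -0.68, with 15 genes higher and 108 lower. Among the 2423 genes of highest GC content, 59.9% to 78.2%, the median was 0.35, with 574 higher and 41 lower. Of the 1190 genes called higher, 829 were also called after the GC and length correction and 210 with each of the 6 libraries left out in turn. Of the 425 called lower, 319 were also called after the correction, 35 with each library left out, and 5 changed sign with the correction.

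**Figure D3:**
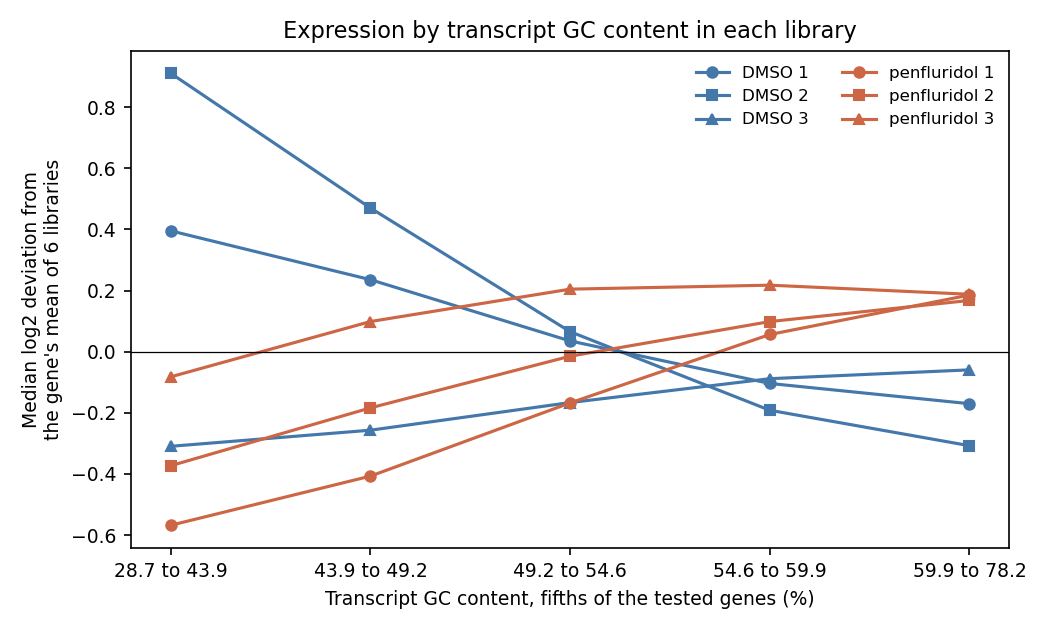
Median log2 deviation of a gene from its mean over the 6 libraries (y axis) in 5 bins of the tested genes by transcript GC content in percent (x axis), as 1 line per library, DMSO in blue and penfluridol in red. DMSO 2 runs from 0.91 in the lowest bin to -0.31 in the highest, DMSO 3 from -0.31 to -0.06, and penfluridol 1 from -0.57 to 0.19.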

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

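The alternatives with a GC and length correction, median-of-ratios scaling or protein-coding genes alone were chosen after seeing the data, and the others before. The alternatives listed beforehand that need read counts (DESeq2 and its size factors, limma-voom and total-count scaling) were not run, since the table holds TPM. With the replicate block 62 genes were higher and 12 lower, and the same 62 and 12 were at least 2-fold. Libraries with the same number did not deviate together (correlations of -0.0081, -0.0061 and -0.348), and the block left the side of the threshold of every gene list as it was. The number of lower genes, 425, was 194 without a filter (83 at least 2-fold, against 224), 719 with median-of-ratios scaling (426 at least 2-fold), 1014 after the GC and length correction and 1321 after it without DMSO 3 (386 at least 2-fold). The cause was not tested. With 1 library left out, 214 to 1732 genes were higher and 42 to 2380 lower, at least 2-fold 197 to 495 and 38 to 1686. Fits with 1 library less have less power, but the highest counts came without DMSO 3. Among 45 called named genes, 45 were called with a pseudocount of 0.1, 36 without a filter, 42 with median-of-ratios scaling, 40 after the GC and length correction and 16 with the replicate block. Without DMSO 1, 2 or 3 they were 26, 37 and 45, and without penfluridol 1, 2 or 3 they were 30, 27 and 41. Named genes that changed sign were COL1A1 (-0.17 after the correction, -0.14 after it without DMSO 3), MT-ND3 (0.051 and 0.25) and ATP5MC3 (0.14 without DMSO 3). COL1A1 ranged from -0.201 to 0.326 with 1 library left out.

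With an estimated correlation 0 gene lists passed. The adjusted p-values became 0.157 for ATF4 targets, 0.157 for NF-kB targets, 0.165 for the interferon response, 0.169 for oxidative phosphorylation, 0.169 for histones, 0.375 for NRF2, 0.388 for immediate early genes, 0.388 for mitosis, 0.579 for lysosome and autophagy, 0.625 for S phase and 0.698 for heat shock. After the GC and length correction, with all libraries and without DMSO 3, the unfolded protein response passed (0.0442 and 0.04485), as did MYC targets (0.0470 and 0.00543), while oxidative phosphorylation did not (0.0691 and 0.544). With 1 library left out the NRF2 list ranged from 0.0117 to 0.0902. The depth is unknown and limits what can be said of genes near 0 TPM.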

Other observations

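Pathways named in the deposited table were tested beside the fixed lists, a test chosen after seeing the data. Of 310 entries of the pathway field, 1 of which was the placeholder "None" with 163 genes, 3 pathways were called higher and 5 lower with camera's preset correlation, none of them with an estimated correlation (adjusted p = 0.998 for each of the 8). After the GC and length correction 6 were called. Systemic lupus erythematosus, DNA replication, alcoholism, base excision repair and glutathione metabolism were lower, and SNARE interactions in vesicular transport were higher. The NF-kappa B pathway had 16 of 55 genes higher and none lower (adjusted p = 0.0101, and 0.0703 after the GC and length correction). Among its members the urokinase gene PLAU rose by a log2 fold change of 1.91 (SE 0.15, adjusted p = 0.00129). Of 74 cytokine and cytokine receptor genes 18 rose and 2 fell (adjusted p = 0.0223, and 0.181 after the correction). They included TNFRSF14, with a log2 fold change of 2.02 (SE 0.23, adjusted p = 0.00377), and the chemokine receptor CXCR4, with -1.96 (SE 0.24, adjusted p = 0.00462). Osteoclast differentiation, with 16 of 68 genes higher and 2 lower (adjusted p = 0.0471, and 0.115 after the correction), was led by SQSTM1, NFKB2 and AP-1 genes that the fixed lists also hold. The pathway with the smallest p was systemic lupus erythematosus, in which 13 of 46 members fell and 3 rose (adjusted p = 0.00961, and 0.00057 after the correction), and those that fell included histone genes such as H4C12 (log2 fold change -2.88, SE 0.28, adjusted p = 0.00227). Spliceosome genes fell in 16 of 142 cases and rose in 5 (adjusted p = 0.0101, and 0.255 after the correction). DNA replication (adjusted p = 0.0101), the proteasome (0.0223) and the cell cycle (0.0485) were lower with 1, 2 and 5 members down and 1, 1 and 9 up. After the correction DNA replication passed (0.00650), and the proteasome (0.139) and the cell cycle (0.0593) did not. CDKN1A, the cyclin-dependent kinase inhibitor p21, was among the cell cycle genes that rose (log2 fold change 1.50, SE 0.15, adjusted p = 0.00252).

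Some genes are often used as references for quantitative PCR. Of these PPIA, whose many pseudogenes can share its reads, fell from 3520 ± 76.9 to 1732 ± 282 TPM (log2 fold change -1.03, SE 0.14, adjusted p = 0.00628, limma, n = 3 per group), while HPRT1 had -1.40 (adjusted p = 0.0691), ACTB -0.49 (0.0553), SDHA 0.21 (0.176) and TBP 0.11 (0.739). With the GC and length correction HPRT1 was called at -0.71 (0.0237), ACTB at -0.82 (0.00836), GAPDH at -0.55 (0.0354, against -0.33 and 0.118 before it), YWHAZ at -0.65 (0.0420, against -1.12 and 0.102) and B2M at 0.66 (0.00890, against -0.04 and 0.925). Of 14 endometrial and Müllerian epithelial markers 9 had a mean of at least 1 TPM, among them PAX8 at 50.4 to 79.0 TPM and MSX1 at 107 to 177 TPM over the 6 libraries. ESR1 was listed at 0 in 5 libraries and at 0.330 TPM in penfluridol 3, and PGR at no more than 0.0700 TPM.

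The tests below were chosen after their results were seen, except those of scaling and of other splits. GC-rich transcripts were higher and AT-rich ones lower with penfluridol. The idea that DMSO 3 was exposed to the drug or mixed up with a treated library is argued against by the ATF4 list, whose members in DMSO 3 differed from the mean of DMSO 1 and 2 by a median of -0.124 (quartiles -0.625 to 0.118), with 12 of 31 above both. A GC bias of single libraries may account for the trend, since DMSO 3 differed from DMSO 1 and 2 along GC with a Spearman's rho of 0.693 across genes, with no drug involved. A drug effect on GC-rich transcripts stays open and cannot be told apart from it, because 3 libraries against 3 give an exact p of 0.1 at best, which was the value.

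The rise of ATF4 targets is not accounted for by 2 technical explanations. Removal of the GC and length trend left the list's median log2 fold change at 1.031, and scaling by median of ratios, which is not set by a few abundant genes, left it at 1.286, against 1.279 as deposited. No biological explanation was tested, since what lies upstream of these transcripts was not measured here.

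In 13 of 25 ribosomal RNA genes all penfluridol values lay below all DMSO values, against 1470 of 10628 protein-coding genes and 5% by chance, with a median log2 fold change of -3.65, and so they did in both ribozyme genes (median -3.70) but in none of 5 ribosomal RNA pseudogenes (median 0.73) or 2 mitochondrial ribosomal RNA genes (median -0.04). The 5S genes among the ribosomal RNA genes are near-identical copies that can share reads, so they are not independent genes to set against that chance. The 35 snRNA genes had a median of -1.72, with 2 of them below in this way and 1 above, and of 26 genes annotated as miscellaneous RNA 4 lay below and 2 above. Uneven carry-over of RNA without a poly(A) tail may be a source, since the share of small non-coding RNA varied 5.786-fold among the 3 DMSO libraries alone. Lower output of RNA polymerase III, which makes 5S RNA but not intron-derived snoRNAs, cannot be told apart from it, although RNU2-1, which RNA polymerase II makes, fell too (adjusted p = 0.00207). The 52 snoRNAs and scaRNAs had a median of -1.302, with quartiles from -1.585 to 0.115, and 3 of them (5.77%) had all penfluridol values below all DMSO values (one-sided binomial p = 0.485). That test takes genes of the same 6 libraries as independent trials, which they are not, so its p decides nothing.

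The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each result 1 split, the real one, gave a value as large. The real split gave 1190 genes higher, 425 lower, 423 at least 2-fold higher, 224 at least 2-fold lower and 11 gene lists. None of the other 9 gave more than 1 gene in either direction, whether or not at least 2-fold. Each of them mixes both treatments within its groups, so a difference between treatments adds to the spread, and few gene calls were likely. Each of the other 9 also gave 3 to 8 gene lists. The sides of such a split hold unequal numbers of the treatments, so part of any treatment difference stays between its groups. These list counts therefore cannot show how readily the set test with the preset correlation passes lists where no difference exists.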
